A study of Homo sapiens with 6 samples.

How the data were processed

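The data are RNA-seq libraries of primary human dermal fibroblasts, 3 kept for 72 h in control medium and 3 in that medium with endothelial cell-derived extracellular vesicles (ECEVs). Per the labels' protocols, cells were confluent before treatment, RNA was taken up in Trizol and purified on columns, and a service provider made and sequenced the libraries. Per the labels, reads were mapped to GRCh38 (hg38) with HISAT2 2.0.5, assembled with StringTie 1.3.3b and counted per gene with featureCounts 1.5.0-p3. The annotation release, the strand setting of the counting and the version of DESeq2 are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

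The deposited gene table holds raw counts per gene and library, made by the authors with featureCounts per the labels. The authors' deposited table of differential genes repeats these counts and adds, per the file headers, normalized values, FPKM, a log2 fold change and p-values. The counts were identical in both tables for all 6 libraries. The normalized values, a signal per gene in the authors' deposited table, are counts divided by 1 size factor per library, from 0.878 to 1.127. The FPKM of the authors' deposited table were computed from those normalized values, since FPKM times gene length over normalized count gave 47.906 in every library, so they were scaled to a common depth. The log2 fold changes and p-values of the authors' deposited table cover genes with an absolute log2 fold change of at least 1 and an adjusted p of at most 0.0499. A DESeq2 1.42.0 run on the counts with the same limits gave 2093 genes, all of which are in that table. Gene names, lengths and coordinates are those of the deposited table. Of its 58735 gene IDs 58207 are in GENCODE release 44, and 99.97% of those overlap the same gene there.

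Tests ran on the raw counts in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), libraries were scaled by TMM, and the robust quasi-likelihood test compared the 2 groups, two-sided and with no covariate, at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. CPM values use the TMM-scaled library sizes. The common dispersion corresponded to a biological coefficient of variation of 8.52%. Depth ran from 18646894 to 24214469 counts per library, so 3 counts, the floor used where a group had none, correspond to 0.124 to 0.161 CPM in a library. Count ratios, their intervals and fold bounds against a floor use library totals without TMM scaling. Intervals and floors cover counting error only. The chi-square statistic per degree of freedom over genes with at least 20 counts in a pair of libraries ran from 2.35 to 4.99 among control pairs, from 6.84 to 21.5 among ECEV pairs and from 95.8 to 152 between groups, so no pair matched within sampling noise.

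Before the data were examined, 32 gene lists with 741 entries were fixed, covering matrix, contractile, signalling, cell cycle, metabolic, stress and cell type genes. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry, adjusted over the lists. The rule for named genes was also fixed before. It took the 8 largest rises and falls among called protein-coding genes with an average of at least 1 log2 CPM and no overlap between groups, the 4 genes of lowest p in each direction, in each list the 3 members of lowest p, in marker lists of other cell types also the 3 most abundant members, and the most abundant member of a list where a sentence needed it. Y-linked genes and XIST were left out of all named genes, and some other genes that the rule names are not reported here. The genes *COL6A3*, *ELN*, *DCN*, *PLAU*, *PLAT*, *ID1*, *CCN2*, *ASNS*, *ATF4*, *CHAC1*, *LDHA*, *CXCL1*, *CSF3*, *FGF10*, *VEGFA*, *MT2A*, *ITGA2*, *ITGA10*, *NPC1*, *PECAM1*, *CLEC14A*, *VWF* and *PRRX1* fall outside the rule and were chosen after their values were seen, as were the genes named in the closing observations.

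The procedure was tested on simulated counts of the 16057 genes for this comparison, with 200 genes changed. It recovered 66%, 82%, 94% and 98% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 10 false calls. With no gene changed edgeR made 0 calls, with 741 genes at an unadjusted p under 0.05. Moving the members of 1 list together gave that list a camera adjusted p of 3.6e-56, and 1 other list was called.

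Alternatives were DESeq2's size factors, upper-quartile scaling and library totals alone, no filter and a filter at an average of 1 log2 CPM, protein-coding genes only, DESeq2's Wald test, limma-voom, the replicate number as a block, leaving out each library in turn, and thresholds with a 2-fold minimum or an adjusted p under 0.01. Removal of each library's trend with gene length and GC content (mgcv 1.9.3) was added after seeing the data, and 99.5% of the tested genes had both values.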

Results

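Polyadenylated RNA was sequenced from primary human dermal fibroblasts, the cells that build and remodel the collagen matrix of the skin. The cultures had reached confluency and were then kept for 72 h either in exosome-depleted control medium or in that medium with extracellular vesicles from endothelial cells (ECEVs), membrane-bound particles that carry RNA, protein and lipid between cells. Each group held 3 libraries. The summed gene counts were 23645819, 24214469 and 19055060 in control replicates 1, 2 and 3 and 18646894, 19390686 and 20970952 in ECEV replicates 1, 2 and 3. The labels do not state whether the replicates were separate cultures or donors, so the p-values measure only the spread between these 6 libraries, which may be technical. Expression is given as edgeR's CPM (counts scaled to a common library total), mean ± SD over 3 libraries per group, and each log2 fold change is ECEV over control with its standard error (SE).

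The comparison of the 2 groups asks how the vesicles altered gene expression in fibroblasts, in a study of skin wound healing. In the ECEV cultures, genes of DNA replication and mitosis, several secreted proteases and the growth factor gene *HGF* were higher, and genes of the contractile apparatus, of many matrix proteins and of amino acid supply were lower. *TOP2A*, the DNA topoisomerase of dividing cells, rose from 74.3 ± 2.8 to 306 ± 11.6 CPM. *MMP1*, the interstitial collagenase, rose 30.9-fold, from 148 ± 26.2 to 4575 ± 1680 CPM (edgeR adjusted p = 0.000687), and *HGF*, hepatocyte growth factor, rose 12.4-fold, from 16.2 ± 1.68 to 202 ± 28.1 CPM (edgeR adjusted p = 3.04e-08). *COL1A1*, the collagen I alpha 1 chain, fell from 22580 ± 1910 to 10880 ± 177 CPM (edgeR adjusted p = 4.06e-08), and *TAGLN*, an actin-binding protein of contractile cells, fell from 339 ± 8.11 to 72.7 ± 5.3 CPM.

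Of the 58735 genes in the count table, 32099 had at least 1 count and 16057 passed the filter on low counts. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7201 of the 16057 genes (44.8%), of which 3620 were raised and 3581 lowered. With library totals alone as the scaling, the split was 5031 raised and 2721 lowered, and the median log2 fold change of the tested genes moved from -0.003 to 0.103, so changes are reported relative to the composition-adjusted scaling. The exceptions are the count ratios and fold bounds given for genes with few counts, which use library totals. At least 2-fold changes were found in 2068 of the called genes, 1000 raised and 1068 lowered, and changes of at least 8-fold in 104 raised and 115 lowered genes. In 3721 called genes the change was under 1.5-fold. The 3 ECEV libraries lay wholly above or wholly below the 3 control libraries for 55.5% of the tested genes, against 10% by chance. The first principal component, which separated the groups, held 78.2% of the variance.

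**Figure D1:**
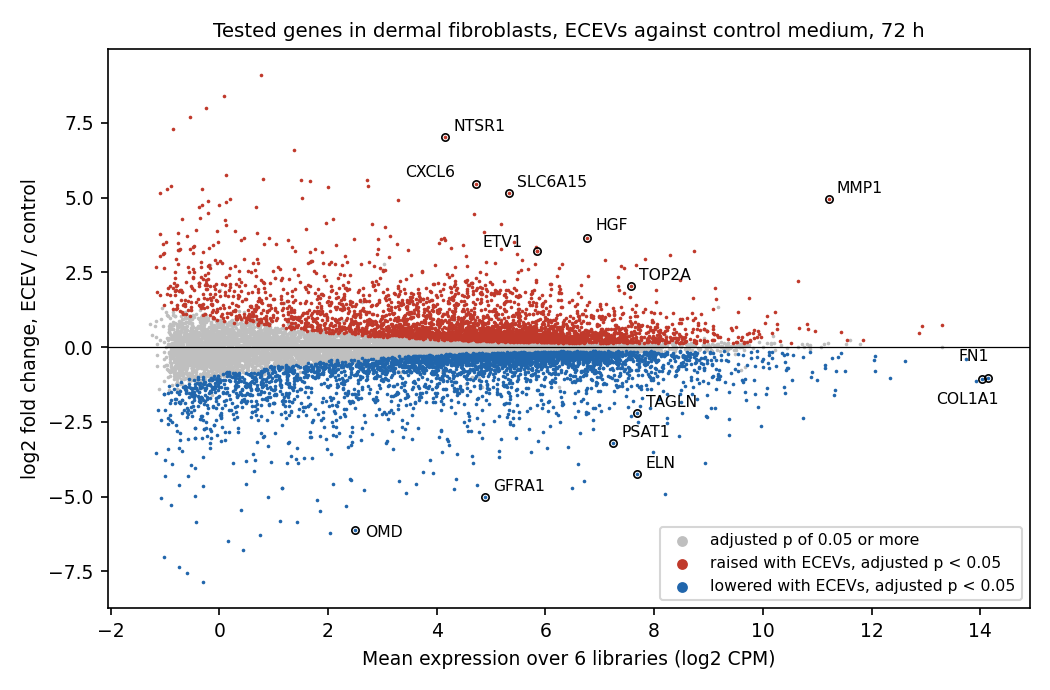
Each point is a tested gene, with its mean expression over the 6 libraries on the x axis (log2 CPM) and its log2 fold change, ECEV over control, on the y axis. Red points are the 3620 raised genes, blue points the 3581 lowered genes and grey points the rest, and named genes are circled, among them *NTSR1* at 7.04 and *GFRA1* at -5.03.

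The largest rises among protein-coding genes above an average of 1 log2 CPM included receptors and secreted factors. *NTSR1*, the neurotensin receptor (ENSG00000101188, chromosome 20, 62708837 to 62762771 in GRCh38), rose by a log2 fold change of 7.04 (SE 0.31), from 0.261 ± 0.043 to 35.4 ± 9.11 CPM (edgeR adjusted p = 1.24e-07). *TACR1*, the receptor of substance P, rose by 5.55 (SE 0.35), and *CXCL6*, a chemokine that attracts neutrophils, by 5.47 (SE 0.65). *CBLN2*, a secreted organiser of synapses, rose by 5.37 (SE 0.35) and *SLC6A15*, a neutral amino acid transporter, by 5.14 (SE 0.62). *PTPN22*, a tyrosine phosphatase of immune cells, had 3 counts in the control libraries together and 306 in the ECEV libraries. By library totals, that is a ratio of 116 with a 95% counting interval of 39.2 to 564. *FP565260.3* rose by 5.58 (SE 0.60), but it is a near-identical copy of *ICOSLG* and the 2 cannot be separated with certainty by read counting. *MYH15*, a myosin heavy chain, rose 40.5-fold, and without control replicate 2 its control libraries held 3 counts and the ECEV libraries 473. By library totals, unlike that fold, the latter is a ratio of 114 with a 95% counting interval of 38.8 to 555. The 4 raised genes of lowest p were *ETV1*, an ETS transcription factor, with a log2 fold change of 3.21 (SE 0.08), *TOP2A* with 2.04 (SE 0.06), *HMGA2*, a chromatin protein of proliferating and embryonic cells, with 2.05 (SE 0.06), and *CENPF*, a kinetochore protein, with 2.07 (SE 0.06).

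Among the largest falls, *GFRA1*, a receptor of glial cell line-derived neurotrophic factor, went from 56.9 ± 4.67 to 1.73 ± 0.57 CPM, a log2 fold change of -5.03 (SE 0.15, edgeR adjusted p = 5.47e-10). *OMD* and *ASPN*, neighbouring small leucine-rich matrix proteins on chromosome 9, had log2 fold changes of -6.13 (SE 0.53) and -5.33 (SE 0.34). *TNFSF18*, a ligand of the tumour necrosis factor family, had -5.85 (SE 0.46), *OLR1*, a receptor of oxidised lipoprotein, -5.80 (SE 0.48), *TINAGL1*, a matrix protein, -5.47 (SE 0.36), and *C11orf87* -5.12 (SE 0.39). Few reads remained for these 6 genes in ECEV cultures, and the fitted size depended on single libraries. Their count ratios and fold bounds are by library totals. Without ECEV replicate 2 the log2 fold changes were -6.51 for *ASPN* and -5.95 for *C11orf87*, *OMD* had 0 counts left in the ECEV libraries, which is at least 137-fold lower against a floor of 3 counts over the group, and *OLR1* had 1 count left, a ratio of 0.0065 with a 95% counting interval of 0.000164 to 0.0365. Without ECEV replicate 3 the log2 fold changes were -5.51 for *OMD* and -5.21 for *OLR1*, and *TNFSF18* had 2 counts left, a ratio of 0.011 with an interval of 0.00132 to 0.0399. Without ECEV replicate 1 *TINAGL1* had 3 counts left, a ratio of 0.0113 with an interval of 0.00233 to 0.0333. The 4 lowered genes of lowest p were *PSAT1*, an enzyme of serine synthesis (ENSG00000135069, chromosome 9, 78297143 to 78330093), with -3.20 (SE 0.07, edgeR adjusted p = 3.41e-11), *OXTR*, the oxytocin receptor, with -3.04 (SE 0.08), *ADM2*, a peptide hormone, with -3.89 (SE 0.10), and *TAGLN* with -2.22 (SE 0.06).

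**Figure D2:**
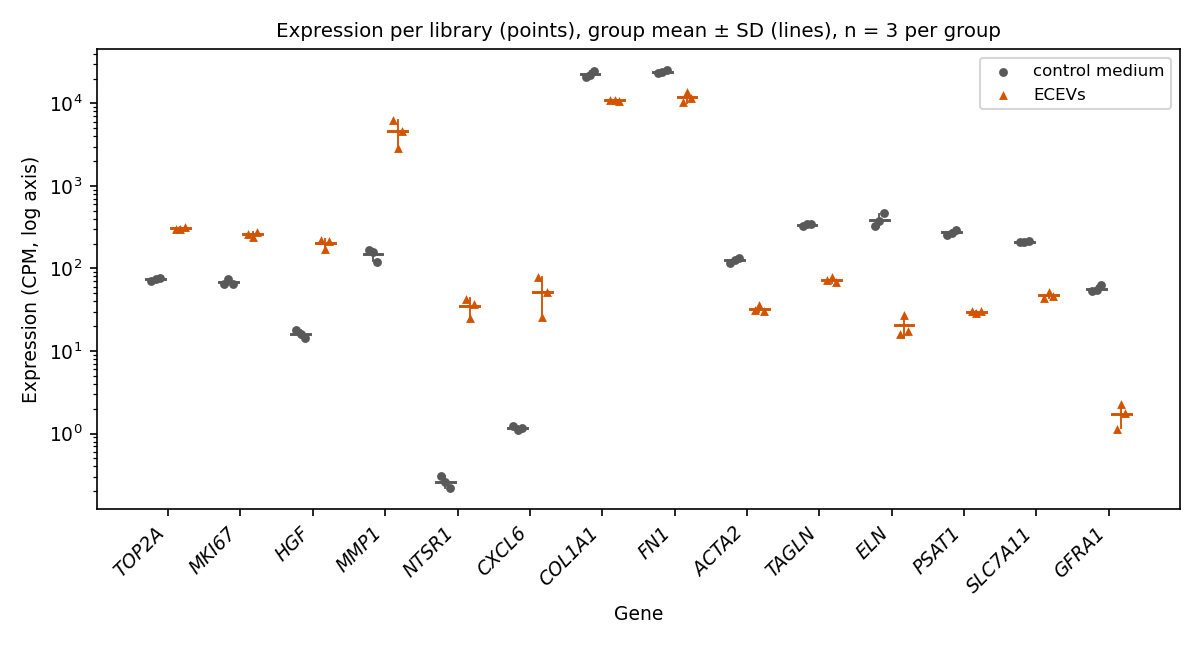
Expression of 14 genes in each library is plotted as CPM on a log axis, with circles for the 3 control libraries, triangles for the 3 ECEV libraries, and lines for the group mean ± SD. *MMP1* lies between 119 and 169 CPM in control and between 2880 and 6240 CPM in ECEV libraries, and *ELN* lies between 328 and 470 CPM in control and between 16.2 and 27.6 CPM in ECEV libraries.

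Genes were then read by 32 lists, of which 29 had at least 5 tested members and a set test. Camera with a preset inter-gene correlation of 0.01 called 5 lists raised and 8 lowered. With the correlation estimated from the 6 libraries camera called 0 lists, with 4 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move on balance in one direction, called 19, namely those 13 and the lists of collagens, growth factors, lipid handling, oxidative stress, fibroblast identity and pericyte markers. In every other even split of the 6 libraries, camera with the preset correlation also called 4 to 10 lists. Those splits each mix control and ECEV libraries, so part of the group difference can remain in them. They do not show whether such a call is particular to the real grouping. Where the count of members past the threshold adjusted over the list alone differed from that over all genes tested, both are given, and elsewhere they were the same.

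Cell division genes rose throughout. Of the mitosis and G2/M list, 30 of 30 members were raised, with a median log2 fold change of 1.92 (camera adjusted p = 5.21e-21, and adjusted p = 0.251 with an estimated correlation). *MKI67*, the proliferation antigen Ki-67, rose from 68.4 ± 6.04 to 260 ± 15.5 CPM. Of the DNA replication and G1/S list, 27 of 27 tested members were raised, with a median of 1.24 (camera adjusted p = 1.84e-13, and adjusted p = 0.315 with an estimated correlation). *RRM2* and *RRM1*, the subunits of ribonucleotide reductase, had log2 fold changes of 1.84 (SE 0.10) and 1.10 (SE 0.06), and *MCM4* and *MCM7*, of the replicative helicase, 1.45 (SE 0.07) and 1.09 (SE 0.08). Targets of p53 and arrest genes went both ways, with 7 raised and 8 lowered of 22 (median 0.08, mean -0.10, camera adjusted p = 0.802). Among these *SESN2*, a stress sensor, went from 50.6 ± 6.33 to 25.2 ± 1 CPM, *BBC3*, a promoter of apoptosis, from 23.6 ± 1.86 to 10.9 ± 1.79 CPM, and *CDKN1A*, the cyclin-dependent kinase inhibitor p21, from 461 ± 20 to 345 ± 25.7 CPM.

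The contractile and myofibroblast list had 15 of 18 members lowered and 3 not past the threshold over all genes tested, and 16 lowered adjusted over the list alone. Its median was -1.40 (camera adjusted p = 5.74e-08, and adjusted p = 0.300 with an estimated correlation). *ACTA2*, the smooth muscle actin that marks myofibroblasts, fell from 126 ± 8.58 to 32.7 ± 2.64 CPM. *TRPC6*, a cation channel, had a log2 fold change of -3.08 (SE 0.11), and *FLNA*, an actin crosslinker and the most abundant member, -0.80 (SE 0.05). Of 21 targets of YAP and TEAD, transcription factors that respond to cell tension, 16 were lowered and 3 raised, with a median of -0.75 (camera adjusted p = 0.000818, and adjusted p = 0.292 with an estimated correlation). *LATS2*, a kinase that restrains YAP, and *CCN2* (*CTGF* in the deposited table), a matricellular protein, had log2 fold changes of -0.89 and -1.04, and *IGFBP3*, the most abundant member, fell from 1535 ± 178 to 385 ± 79.1 CPM, while *NT5E* and *FJX1* rose by 1.61 and 1.63. The 20 TGF-beta and SMAD targets moved apart, with 7 raised and 6 lowered over all genes tested, 8 raised and 6 lowered adjusted over the list alone, and a median of 0.16 (camera adjusted p = 0.618). In this list *COMP*, *TGFBI* and *LTBP2*, matrix proteins, rose by 1.16, 0.54 and 0.48, and *ID1*, an inhibitor of differentiation, by 2.52. *BAMBI*, a pseudoreceptor, had a log2 fold change of -3.56 (SE 0.25), and *CCN2*, at -1.04, is a member of this list as well.

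The 3 most abundant transcripts that fell encode matrix proteins. *FN1*, *COL1A1* and *COL1A2* together held 6.56% ± 0.35 of the counts in control and 3.38% ± 0.28 in ECEV libraries (SD, n = 3). Of 20 fibrillar and network collagens, 11 were lowered and 7 raised (median -0.43, camera adjusted p = 0.314). *COL1A1*, *COL1A2* and *COL12A1* had log2 fold changes of -1.05, -1.12 and -0.99 (SE 0.06, 0.07 and 0.06), and *COL6A3* rose by 0.75 (SE 0.05). Of 24 matrix glycoproteins and proteoglycans, 16 were lowered and 5 raised over all genes tested, and 16 and 6 adjusted over the list alone, with a median of -0.97 (camera adjusted p = 0.00352, and adjusted p = 0.251 with an estimated correlation). *FMOD*, *SPARC* and *HAPLN3* had log2 fold changes of -1.35, -1.43 and -2.76, *DCN*, decorin, -1.60, and *FN1*, fibronectin, -1.02 (SE 0.09). Of 26 elastic fibre and crosslinking genes, 16 were lowered and 7 raised, with a median of -0.47 (camera adjusted p = 0.0358, and adjusted p = 0.315 with an estimated correlation). *ELN*, elastin, fell from 391 ± 72.5 to 20.5 ± 6.19 CPM (edgeR adjusted p = 0.00025). *FBLN5* and *FBLN1*, fibulins, had log2 fold changes of -0.87 and -0.37, while *LTBP1*, which holds latent TGF-beta in the matrix, and *P4HA3*, a prolyl hydroxylase, rose by 1.52 and 2.31.

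Matrix proteases and their inhibitors moved in both directions. Of 27 tested members 10 were raised and 10 lowered over all genes tested, and 12 and 10 adjusted over the list alone. The median was 0, the mean 0.50, and the direction was up by camera (adjusted p = 0.802) and down by fry. *MMP1* (ENSG00000196611, chromosome 11, 102789920 to 102798160), *PLAT* and *PLAU*, the plasminogen activators, had log2 fold changes of 4.95 (SE 0.40), 3.20 (SE 0.27) and 2.72 (SE 0.31). *TIMP3*, an inhibitor of metalloproteases, *ADAMTS5*, an aggrecanase, and *CTSK*, a collagen-degrading cathepsin, had -1.35 (SE 0.05), -2.16 (SE 0.10) and -0.81 (SE 0.07). Integrins and adhesion genes were likewise divided, with 10 raised and 10 lowered of 23 over all genes tested, and 10 and 11 adjusted over the list alone (median 0, mean 0.18, direction down by camera, adjusted p = 0.971). *ITGA10* and *ITGA2*, subunits of collagen receptors, rose by 4.12 and 2.73 and *ITGB1* by 0.53, and *ITGA11*, another collagen receptor subunit, *ITGAV* and *ITGA4* had log2 fold changes of -2.20, -1.16 and -1.27.

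**Figure D3:**
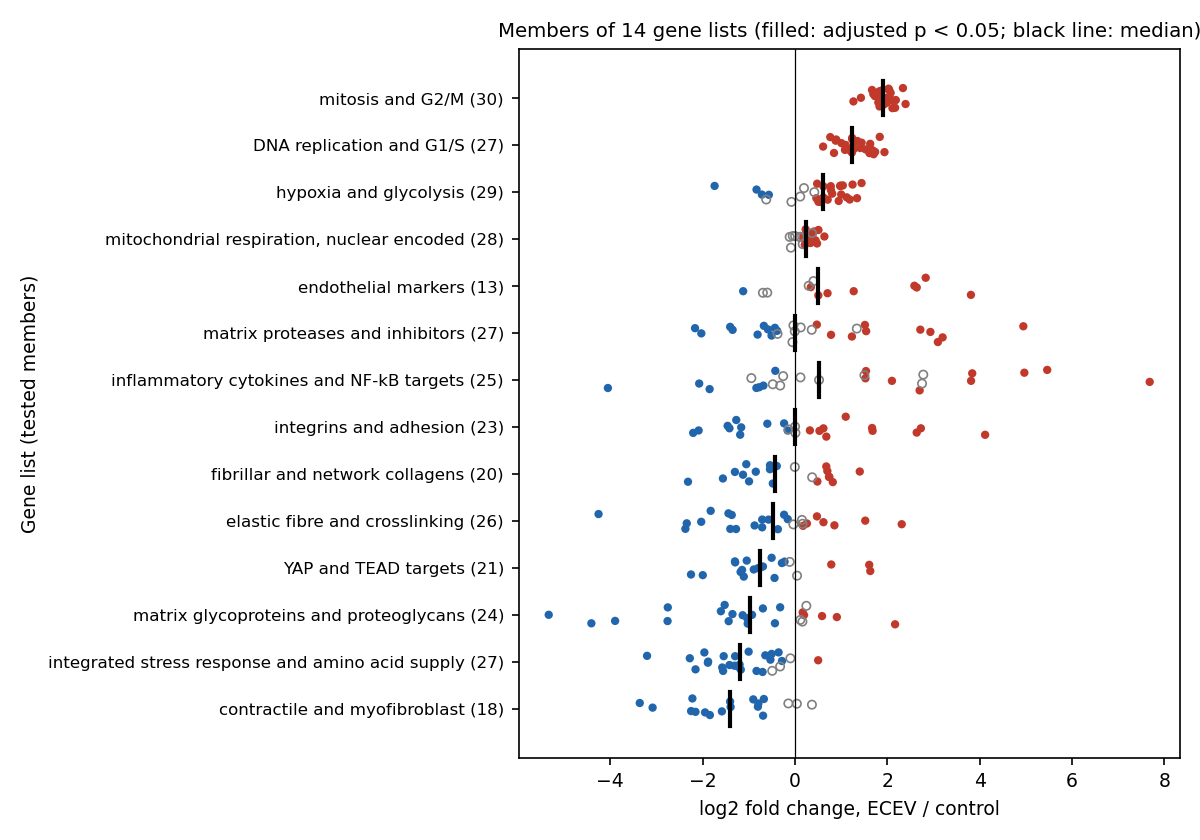
Each point is a tested member of 1 of 14 gene lists, placed on the x axis by its log2 fold change, ECEV over control. Filled points passed an adjusted p of 0.05 (red raised, blue lowered), open points did not, and the black line is the list's median, which ran from 1.92 for mitosis and G2/M to -1.40 for contractile and myofibroblast genes.

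Genes of amino acid supply and the integrated stress response, which ATF4 drives, fell. Of 27 members 23 were lowered and 1 raised, with a median of -1.20 (camera adjusted p = 6.22e-11, and adjusted p = 0.251 with an estimated correlation). *PSAT1* and *PHGDH*, of serine synthesis, had log2 fold changes of -3.20 (SE 0.07) and -1.88 (SE 0.07), *SLC7A11*, the cystine transporter, -2.15 (SE 0.07), *ASNS*, asparagine synthetase, -1.96 (SE 0.24), *ATF4* itself -0.64 (SE 0.05), and *SLC38A2*, the most abundant member, -0.28 (SE 0.06). The raised member was *CHAC1*, a glutathione-degrading enzyme, at 0.50 (SE 0.10). The unfolded protein response list had 5 raised and 7 lowered of 22 (median 0.01, mean -0.10, camera adjusted p = 0.713), with *HERPUD1*, *SEL1L* and *XBP1* at -0.92, -0.76 and -0.63. Heat shock genes had 8 raised and 6 lowered of 17 (median 0.20, up by camera with adjusted p = 0.679, down by fry). The small heat shock proteins *HSPB1* and *CRYAB* had -0.57 and -1.07, and the mitochondrial chaperone *HSPD1* rose by 0.74.

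Of 29 hypoxia and glycolysis genes, 20 were raised and 4 lowered over all genes tested, and 22 and 4 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 0.000226, and adjusted p = 0.583 with an estimated correlation). The glycolytic enzymes *GAPDH*, *PGAM1*, *LDHA* and *PKM* rose by 0.78, 0.98, 1.19 and 0.62, and *SLC2A1*, the glucose transporter, had a log2 fold change of -0.71 (SE 0.05). Of 28 nuclear genes of mitochondrial respiration, 20 were raised and 8 not past the threshold over all genes tested, and 21 were raised adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.000116, and adjusted p = 0.292 with an estimated correlation). Examples were *SDHA* and *UQCRQ* at 0.39 and 0.48. Of the 13 mitochondrially encoded transcripts, 2 were raised and 1 lowered (median 0.10, camera adjusted p = 0.435), with *MT-CO2* at 0.52, *MT-CO3* at 0.22 and *MT-ND1* at -0.32, and all mitochondrial transcripts together took 2.98% ± 0.11 of the counts in control and 3.43% ± 0.17 in ECEV libraries (SD, n = 3). Ribosomal protein genes had 5 raised and 4 lowered of 30 over all genes tested, and 3 and 3 adjusted over the list alone (median 0.07, camera adjusted p = 0.594). Their lowest p values belonged to *RPS23*, *RPLP1* and *RPS24* at -0.24, -0.22 and 0.23, and *RPLP1* was no longer called with library totals alone (-0.12).

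Of 25 cholesterol synthesis genes, 13 were lowered and 5 raised over all genes tested, and 14 and 5 adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.0491, and adjusted p = 0.753 with an estimated correlation). The list's camera call was lost without control replicate 1 (adjusted p = 0.0858), control replicate 2 (0.0993), ECEV replicate 2 (0.204) or ECEV replicate 3 (0.0606), with DESeq2's size factors (0.0516), with library totals alone (0.0552) and in the replicate block (0.0627), and the camera adjusted p ran from 0.00936 to 0.753 over its 12 alternatives. Fatty acid and lipid handling genes had 10 raised and 4 lowered of 22 (median 0.05, camera adjusted p = 0.542), with *FABP3*, *PLIN3* and *ELOVL6* at -1.37, 0.57 and 0.77. Of 26 lysosome and autophagy genes, 16 were lowered and 3 raised over all genes tested, and 17 and 3 adjusted over the list alone, with a median of -0.25 (camera adjusted p = 0.00733, and adjusted p = 0.300 with an estimated correlation). *LAMP1* and *CTSD* had -0.68 and -0.84, while *CTSL*, a cathepsin, and *NPC1*, a lysosomal cholesterol transporter, rose by 1.65 and 1.45. Oxidative stress genes and metallothioneins had 10 lowered and 5 raised of 19 (median -0.31, camera adjusted p = 0.0592). *FTH1* and *FTL*, the ferritin chains, both had a log2 fold change of -1.10, and *MT2A*, a metallothionein, rose by 2.95 (SE 0.26). That list was called lowered without ECEV replicate 1 (camera adjusted p = 0.0491), above an average of 1 log2 CPM (0.013), with library totals alone (0.0283) and by fry (adjusted p = 0.000469), in a range of 0.000469 to 0.315 over its alternatives.

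Inflammatory genes did not move as 1 group. Of 25 cytokines and NF-kB targets, 9 were raised and 7 lowered over all genes tested, and 12 and 8 adjusted over the list alone (median 0.52, camera adjusted p = 0.594). *CXCL1*, a neutrophil chemokine, rose from 3.83 ± 0.49 to 54.6 ± 21.9 CPM and *PTGS2*, the inducible cyclooxygenase, from 6.23 ± 0.51 to 40.7 ± 12.2 CPM. *CSF3*, granulocyte colony-stimulating factor, had 0 counts in the control libraries and 74 in the ECEV libraries. By library totals, that is at least 28.0-fold higher against a floor of 3 counts over the control group. Without ECEV replicate 1, which held 43 of these counts, it is at least 17.1-fold higher, again by library totals. The list's median was the same with *CSF3* at the bound of 28.0-fold. *BIRC3*, *CCL11* and *PTX3*, an apoptosis inhibitor, a chemokine for eosinophils and a soluble pattern receptor, had log2 fold changes of -2.07, -4.05 and -1.85. Of 25 interferon response genes, 12 were lowered and 3 raised over all genes tested, and 14 and 3 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.0234, and adjusted p = 0.583 with an estimated correlation). *GBP1* and *IRF7* had log2 fold changes of -1.18 and -0.81. The interferon call was lost without control replicate 3 (camera adjusted p = 0.0743), in a range of 0.00925 to 0.583 over its alternatives.

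Among 26 angiogenic and fibroblast growth factors, 14 were lowered and 8 raised over all genes tested, and 16 and 8 adjusted over the list alone (median -0.40, camera adjusted p = 0.13, called lowered with library totals alone at 0.0367 and by fry at 0.002, in a range of 0.002 to 0.315 over its alternatives). *HGF* (ENSG00000019991, chromosome 7, 81699008 to 81770438) and *PGF*, placental growth factor, rose by 3.64 (SE 0.12) and 1.55 (SE 0.08), and *VEGFA* by 0.80 (SE 0.07). *ANGPT1*, angiopoietin 1, and *FGF10* had log2 fold changes of -3.05 (SE 0.13) and -3.76 (SE 0.34).

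Markers of cell identity were measured beside these groups. Of 18 dermal fibroblast identity markers, 10 were lowered and 7 raised (median -0.45, camera adjusted p = 0.314), with *DPP4* at -0.97 and *PRRX1*, a mesenchymal transcription factor, at 2.24. Of 28 endothelial markers 13 were expressed highly enough to test, and 8 were raised and 1 lowered, with a median of 0.51 (camera adjusted p = 0.0491, and adjusted p = 0.489 with an estimated correlation). *ESM1* went from 2.29 ± 0.43 to 13.9 ± 5.30 CPM, *ANGPT2* from 0.166 ± 0.080 to 1.25 ± 0.39 CPM, *ENG*, which fibroblasts also express, from 191 ± 8.51 to 243 ± 13.3 CPM, and *PECAM1* from 0.058 ± 0.067 to 0.945 ± 0.35 CPM. The fold of *PECAM1* was 14.1, and without control replicate 1 its control libraries held 1 count and the ECEV libraries 58. By library totals, unlike that fold, the latter is a ratio of 42.5 with a 95% counting interval of 7.34 to 1710. *CLEC14A* had a log2 fold change of -1.12 (SE 0.28), and *VWF* was at 1.38 ± 0.44 and 0.918 ± 0.20 CPM. The endothelial call was lost without control replicate 3 (camera adjusted p = 0.0886), ECEV replicate 1 (0.0679) or ECEV replicate 3 (0.0698), with DESeq2's size factors (0.0516) and with library totals alone (0.128), in a range of 0.00977, by fry, to 0.489 over its alternatives.

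Pericyte and smooth muscle markers had 3 raised and 6 lowered of 12 (median -0.67, camera adjusted p = 0.543). *ANPEP*, a surface peptidase, rose from 569 ± 23.5 to 2624 ± 323 CPM, *NOTCH3* and *CSPG4* rose by 1.33 and 0.37, and *CNN1* and *ACTG2* had log2 fold changes of -1.84 and -2.25. Adipogenic markers had 2 raised and 3 lowered of 8 (median -0.23, mean 0.27, down by camera with adjusted p = 0.891), with *CEBPA* at 2.56, *PNPLA2* at -0.63 and *CFD* at -2.39. Keratinocyte markers had 4 tested members, too few for a set test, with 1 raised and 1 lowered (median -0.24, mean 0.07). *LAMB3* went from 6.77 ± 0.44 to 14.4 ± 1.19 CPM, *KRT10* from 33.3 ± 2.4 to 26.7 ± 2.96 CPM and *DSP* from 18.6 ± 1.5 to 16.7 ± 0.84 CPM. The call of *KRT10* (log2 fold change -0.32) was lost without control replicate 2 (-0.26) and with library totals alone (-0.21). Of 4 tested melanocyte markers 2 were lowered and 2 were not past the threshold (median -0.22), with *MITF* at -1.20 (SE 0.15), *KIT* at -0.52 (SE 0.09) and *MLANA* at 1.12 ± 0.39 and 1.20 ± 0.31 CPM. Of 4 tested leukocyte markers 2 were raised and 2 were not past the threshold (median 0.88), with *CD14* going from 0.903 ± 0.25 to 2.07 ± 0.33 CPM and *CD74* at 1.89 ± 0.32 and 1.77 ± 0.57 CPM. The call of *LAPTM5* (log2 fold change 1.23) was lost without control replicate 1, 2 or 3 (1.08, 1.48 and 1.16), without ECEV replicate 1 or 2 (1.28 and 0.72), with upper-quartile scaling (1.21), with DESeq2 (1.25) and with limma-voom (1.06).

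The authors' deposited table of differential genes lists 2095 genes, 1045 higher and 1050 lower in ECEV cultures. Of these 1935 were tested with edgeR and 1925 were called in the same direction, with 0 in the opposite direction. Of the 2068 genes called here with at least a 2-fold change, 1919 are in the authors' deposited table. Across the 1935 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of edgeR had a Pearson correlation of 0.9997. Both sets of values come from the same counts, and the authors' genes were selected at an absolute log2 fold change of at least 1. Matching directions and a high correlation follow largely from that, so they check the computation only.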

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

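The removal of the trend with gene length and GC content was chosen after seeing the data. The count of 7201 changed genes lay between 5221 and 8273 under the alternatives other than a fold minimum, and leaving out each library in turn gave 5804 (without ECEV replicate 3) to 8273 genes (without ECEV replicate 2). The alternative fits kept 78.9% to 99.6% of the called genes, with 0 shared calls of opposite sign in any of them, DESeq2 (6397 genes) and limma-voom (7192 genes) included. A 2-fold minimum left 2068 genes, since it removes smaller changes by construction. Removing the length and GC trend gave 7186 genes, 3872 raised and 3314 lowered. The replicate block gave 6650 genes and 12 lists, losing the cholesterol synthesis call; libraries of the same number had deviations correlated at -0.010, -0.016 and -0.015, and 0 of the 6 libraries correlated best with its own number. Leaving out 1 library kept 11 or 12 of the 13 called lists, and without ECEV replicate 1 the oxidative stress list was called in addition; fry called 19. Camera with an estimated correlation called 0 lists, with 4 at an unadjusted p under 0.05, and the estimate rests on 6 libraries. A higher correlation is not the cause in every list. For matrix glycoproteins and proteoglycans the estimate was 0.00368, under the preset 0.01, yet the unadjusted camera p went from 0.00097 to 0.0246. What else differs between the settings was not tested. Of 179 named genes 169 kept their side of the threshold and direction in each fit that gave them a value, and none of the other 10 turned direction where called. The simulated recovery was 66% for a log2 change of 0.5, with 200 genes changed and the same dispersion in both groups. The data had 7201 called genes and more spread among ECEV libraries, so that figure is only a guide. A small change that was not called is not shown to be absent.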

Other observations

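The tests of a control-like share, of depth and of endothelial carry-over were chosen only after the results were seen. The MAPK, glucocorticoid, Wnt and Notch lists were fixed after the main results and before those genes were looked at, except *LGR5*, and the set of core endothelial markers was put together after values of some of them had been seen.

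Of 10 outputs of MAPK signalling, the kinase cascade that growth factors switch on, 9 were raised by edgeR in ECEV cultures, with a median log2 fold change of 1.71. As a list they were called with a fixed correlation between genes (limma camera adjusted p = 1.53e-05) and not with an estimated one (limma camera adjusted p = 0.379). The feedback genes *DUSP6*, *DUSP4* and *SPRY4* rose by 2.24 (SE 0.29), 2.41 (SE 0.24) and 2.11 (SE 0.23), the transcription factors *ETV4* and *ETV5* by 1.99 (SE 0.11) and 0.81 (SE 0.06), and *PHLDA1* went from 48.3 ± 4.01 to 299 ± 41.2 CPM (SD, n = 3). Of 12 Wnt and beta-catenin targets 7 were tested, of which 3 were lowered and 4 not past the threshold (median -0.29, limma camera adjusted p = 0.292 over the 3 lists of this part with a set test). *LGR5*, a receptor of R-spondins, had 156 counts in the control and 1 in the ECEV libraries. By library totals, that is a ratio of 0.00727 with a 95% counting interval of 0.000183 to 0.0411. Without ECEV replicate 1, which held the 1 count, *LGR5* was at least 31.4-fold lower, also by library totals, against a floor of 3 counts over the group. *AXIN2*, a feedback gene of the pathway, and *DKK1*, a secreted inhibitor of it, had log2 fold changes of -1.06 (SE 0.19) and -1.24 (SE 0.22). *LEF1*, a transcription factor of the pathway, went the other way, with a log2 fold change of 0.78 (SE 0.30) that was just short of the threshold (edgeR adjusted p = 0.0501) and was called raised in 8 alternatives, those without control replicate 2 (0.97) and without ECEV replicate 2 (0.85) among them. Of 6 Notch targets 3 were tested and 2 raised, *HES1* by 2.72 and *HEYL* by 1.60, but *HES1* was no longer called without control replicate 1, 2 or 3 or ECEV replicate 3 or with no filter on low counts (log2 fold changes of 2.72, 2.98, 2.52, 2.69 and 2.74), nor *HEYL* without control replicate 2 or 3 (1.49 and 1.55).

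The real grouping called 7201 genes, and the highest of the other 9 splits of the 6 libraries into 3 and 3 called 0 by edgeR, with at most 365 at an unadjusted p under 0.05, so 1 of the 10 splits, the real one, gave as many. For lists, by camera with the preset correlation, the real grouping called 13 and the other splits 4 to 10. Again 1 of the 10, the real one, gave as many, but list calls by that test thus also arose in splits with 0 genes called. With 10 splits the share cannot fall under 0.05. Each other split also mixes control and ECEV libraries, so the group difference enters its spread and few gene calls would follow in any case. The contrast of 7201 with 0 genes thus does not weigh against chance. Part of the group difference can also remain between the mixed sides. The list calls in those splits thus do not show how often the test calls lists without it.

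ECEV replicate 2 lay nearer to the controls than ECEV replicates 1 and 3: regressed on the mean treatment effect over the called genes, the slopes of ECEV replicates 1, 2 and 3 were 1.103, 0.877 and 1.020. A difference in depth is argued against, since the total of ECEV replicate 2 lay between those of the other ECEV libraries, and thinning any of the 3 to 0.5 of its counts moved its slope by at most 0.0085. Removing each library's trend with gene length and GC content left a gap of 0.225 between replicates 1 and 2, from 0.226, which argues against that trend. One fixed share of control-like RNA or cells as the whole cause is argued against, within limits. The share had a median of 9.33% over 170 strongly lowered and 32% over 142 strongly raised genes, a gap of 22.6 points. ECEV replicates 1 and 3 against each other gave gaps of -12.4 and 10.4 points, which are 1 pair taken in both directions. That baseline is also unlike the value of ECEV replicate 2, which was set against the mean of 2 libraries. A smaller share and a weaker response in that culture stay open, and no biological explanation was tested because the labels give the replicates no other difference.

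Of 13 tested endothelial markers 8 were raised and 1 lowered (camera adjusted p = 0.0491, and adjusted p = 0.489 with an estimated correlation, in a range of 0.00977, by fry, to 0.489 over its alternatives), and RNA carried over from endothelial cells is a candidate explanation for single markers. For *ESM1*, which rose by 11.6 CPM, whole endothelial RNA is argued against on the core markers only. These 16 markers, put together after some values were seen, rose together by 0.76 CPM, a difference of 10.9 CPM (SE 3.09). Without any 1 of them the rise was at most 2.05 CPM. In the fixed list, 25 markers apart from *ESM1* were under 10 CPM in control cultures, the core markers *PECAM1* and *CLEC14A* among them. Together they rose from 16.2 ± 1.16 to 22.3 ± 0.705 CPM (SD, n = 3), by 6.09 CPM. The rise of *ESM1* exceeded theirs by 5.53 CPM (SE 2.86). That difference is less clear against its SE, so the fixed list does not decide the question. *PECAM1* rose by 0.887 CPM, while the 15 other core markers changed together by -0.127 CPM (SE 0.302), or by 1.16 CPM without *CLEC14A*, which fell. For *PECAM1* carry-over cannot be told apart from expression by the fibroblasts, because that sum depends on 1 marker. *CDH5*, a marker abundant in endothelial cells, had 1 count in the 6 libraries, and RNA of the vesicles, which may hold some transcripts and not others, was not measured here.

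Cell cycle genes, *HGF*, *MMP1* and the metallothionein gene *MT2A* rose together. Growth factor type signalling and a glucocorticoid in the vesicle preparation were examined as candidate explanations, by lists of their targets. Whether a glucocorticoid would raise *HGF* or *MMP1* in these cells was not tested. With 9 of 10 members of the MAPK output list raised (limma camera adjusted p = 1.53e-05, and adjusted p = 0.379 with an estimated correlation), growth factor type signalling is consistent with the data, as a hypothesis. For glucocorticoid, 4 of 8 targets were raised and 3 lowered (median 0.39, limma camera adjusted p = 0.41). *FKBP5* and *GLUL* rose by 1.22 and 1.11, and *TSC22D3* and *DUSP1* had -1.03 and -0.94. A glucocorticoid effect cannot be told apart from others, because its targets went both ways and several also answer to other signals.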
